A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

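RNA of Synechocystis sp. PCC 6803 was measured on 8 custom Agilent arrays in 1 colour (Cy3). Per the labels, total RNA was labelled directly, without cDNA synthesis, so that probes report the strand. The groups were WT and FtsH3down at 0 h and at 24 h of iron depletion, with 2 arrays each, which the labels call biological replicates. Per the labels, the depleted medium held about 5 µM of residual iron and 10 µM of chelator, under white light (40 µmol photons m-2 s-1). Samples were grouped by the strain and time in their titles. The replicate numbers were shared between groups only as numbers, and nothing in the labels paired the cultures.

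The deposited scanner files hold 1 line per spot from Agilent Feature Extraction 10.7.3.1. Per the file headers, the signals are intensity values. The processed signal had its background subtracted and a trend within the array removed, and was not scaled between arrays. Per the file headers, other columns are flags of 0 or 1, which state whether a spot was well above background, an outlier or saturated. The deposited matrix holds log2 values that the authors made with limma, per the labels, in which no version and no settings are given. Its column medians lay between 10.88 and 10.91. Each column correlated across probes with r between 0.9963 and 0.9996 with values of the same array after normexp background correction and quantile normalisation, against 0.967 to 0.978 with the processed signal. The matrix was used as an alternative, not as the main values.

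For the main values, the log2 processed signal of each array had its 75th percentile over non-control spots subtracted. Spots marked as outliers were left out, which left 31 of 20363 probes without a value on some array. The spots of a probe and then the probes of a feature were averaged on the log2 scale. A feature had a median of 2 probes, and 3555 features had a single probe. Of 8830 features, 8805 had values. The 8228 well above background on both arrays of at least 1 group were tested, and 577 were left out as dim. Features were taken as protein-coding when their name was a locus tag or gene without a mark for antisense, untranslated region, part of a gene or non-coding RNA. No spot was marked saturated, and 103 to 211 spots per array lay above 90% of the saturation value.

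The 5 comparisons were FtsH3down against WT at 0 h and at 24 h, 24 h against 0 h in each strain, and the difference of these responses (interaction). Each came from a single limma fit (limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table) over all 8 arrays with 1 coefficient per group, 4 residual degrees of freedom and moderated variances (prior degrees of freedom 4.1). P-values were adjusted by the Benjamini-Hochberg method over the features tested, with a threshold of 0.05. "Rose", "fell", "higher" and "lower" are used of genes that passed it. Because all arrays of a time lay on the same slide, a slide term is absorbed in the strain comparisons and cannot be fitted beside the iron comparisons. As a check within slides, each strain comparison was also fitted on its 4 arrays alone, with 2 residual degrees of freedom. The strain comparisons at both times share no array, and neither do the iron comparisons of both strains. The iron comparisons do share the difference between the slides. With 2 arrays against 2, exchanging arrays between groups gives only 3 splits, so no count over other splits was made. The replicate number showed no shared deviations beyond weak ones (correlations from -0.27 to 0.2 across features), and it was not used as a block in the main values.

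For sets of genes, 22 lists with 312 genes were written, of which 308 were tested. They are FtsH proteases, iron acquisition and iron stress, iron storage, iron-sulfur cluster assembly, phosphate stress, nitrogen control, inorganic carbon uptake, carboxysome and Rubisco, photosystem I, photosystem II, phycobilisome, cytochrome b6f and soluble carriers, ATP synthase, NDH-1 complex, tetrapyrrole and chlorophyll synthesis, ribosomal proteins, chaperones and other proteases, high light and oxidative stress, sigma factors, metal homeostasis other than iron, hydrogenase and respiratory oxidases, and regulators of iron and phosphate responses. Each was tested with camera in limma at a preset inter-gene correlation of 0.01 against protein-coding genes, and p-values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. Gene symbols are commonly used names that were fixed with the lists. The deposited files give locus tags, and the reference table matched 0 of them, so no chromosome positions are given. The lists, the comparisons, the tests, most alternatives and the rule for naming genes were chosen before the data were examined.

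The rule named the 4 FtsH genes and fur in every comparison. It then named up to 10 protein-coding genes and up to 5 non-coding features per direction with the largest changes among those that passed and whose groups' arrays did not overlap (no such condition for the interaction), and up to 4 members per list with the largest changes that passed. Fewer were named in the text, in rank order within each part, and genes outside the rule are marked as picked out after their values were seen. A group counted as under the floor for a feature when no spot was well above background on its arrays, or when its mean lay under the mean of its arrays' lowest signals well above background. This held for 617 features in WT and 965 in FtsH3down at 0 h and for 1015 and 2087 at 24 h. In comparisons of 2 groups a bound on the fold of a named feature is then given in place of the fitted change, and no fold where both groups were under the floor. In the interaction the fitted difference is given and marked as inexact. The second part of this rule was added after the data were seen.

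The procedure was tested on simulated data with the same layout, in which 200 of 8228 features changed. At a log2 change of 1 it recovered 68.5% and 70.5% in the strain comparisons, 67% and 66.5% in the iron comparisons and 21% in the interaction, and at a log2 change of 2 at least 91% in each. With no change, limma made 0 calls. Calls of unchanged features ran from 3 of 45 (interaction) to 17 of 150 (iron comparison in FtsH3down), both at a log2 change of 1. The simulated groups had equal means apart from these changes and the same spread, and scaling was not simulated. The simulation therefore does not show the error rate in the real data, where far more features passed.

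The alternatives were normexp background correction (offset 50) with quantile normalisation, quantile normalisation alone, median scaling, the deposited matrix, no filter or a stricter filter on dim features, the median of the probes, each probe on its own, trended and robust moderation, the 2 compared groups alone, a replicate block, each array left out in turn, stricter thresholds, and the other set tests. Scaling on protein-coding features, a filter on the compared groups, leaving out features near saturation, and camera against all features were added after the data were seen. Some scalings moved the median of all log2 changes by more than 0.1. In the strain comparisons, scaling on protein-coding features moved it by 0.25 at 0 h and 0.3 at 24 h, and at 24 h normexp moved it by -0.12 and the matrix by -0.15. In WT between the times the shift was 0.11 with normexp, 0.17 with quantile normalisation, 0.18 with median scaling and 0.11 with the matrix. It was 0.13 with median scaling in FtsH3down, and -0.11 with quantile normalisation and -0.12 with the matrix in the interaction. Control spots were not analysed here.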

Results

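The arrays measured RNA from Synechocystis sp. PCC 6803, a unicellular cyanobacterium, in a wild type (WT) and in FtsH3down, a strain in which expression of ftsH3 (slr1604) can be turned down. FtsH3 is a subunit of a membrane-bound, ATP-dependent protease. Ammonium, which per the series description induces the knockdown, was present in every culture. Each strain was sampled under standard conditions (0 h) and after 24 h of iron depletion, set up with 10 µM of the iron chelator desferrioxamine B. Each of the 4 groups had 2 arrays, described by the labels as biological replicates, and this number limits the precision of every value. Each array held 42303 spots, of which 40886 were not controls. They reported 8228 tested features, made up of 3299 protein-coding genes and 4929 non-coding features such as antisense RNAs, 5' untranslated regions (5'UTR) and parts of genes.

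The 75th percentile of the background-corrected signal was 4223 and 4797 on the WT arrays at 0 h, 4309 and 2812 on the FtsH3down arrays at 0 h, 4121 and 3336 on the WT arrays at 24 h, and 3170 and 2419 on the FtsH3down arrays at 24 h. The share of spots well above background was 83.5% and 87.2% in WT at 0 h, 78% and 80.9% in FtsH3down at 0 h, and 81.4% and 81.9% in WT at 24 h. It was lowest, at 69.3% and 60.7%, in FtsH3down at 24 h. Across features, replicate arrays correlated with r between 0.987 and 0.996, arrays of the same strain with r between 0.888 and 0.972, and arrays of the same time with r between 0.75 and 0.837. Features are not independent replicates, so these correlations describe the arrays only. All 24 h arrays lay on slide 1 and all 0 h arrays on slide 2, each with its own scan. The strain comparisons were therefore within a slide, whereas the change with iron depletion and the slide cannot be told apart. An additive effect of the slide cancels in the difference between the strains' responses. Values below are log2 signals relative to the array's 75th percentile, and changes are given with the SE of the limma fit. Replicate arrays differed more in FtsH3down (SD of the log2 differences 0.323 at 0 h and 0.394 at 24 h) than in WT (0.192 and 0.228). The fit shares 1 spread per feature over all groups. Its SE and p-values can therefore be too small within FtsH3down and too large within WT.

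The targeted transcript, ftsH3, was lower in FtsH3down at both times. Its signal was 0.26 and 0.33 on the WT arrays and -0.08 and -0.18 on the FtsH3down arrays at 0 h, a change of -0.43 ± 0.14 (n = 2 arrays per group, adjusted p = 0.029 by limma). At 24 h it was 1.32 and 0.98 in WT against -0.41 and -0.52 in FtsH3down, a change of -1.61 ± 0.14 (adjusted p = 1.9e-05). The call at 0 h was lost when any of the 4 arrays of that time was left out (adjusted p from 0.05 to 0.14) and with 3 other scalings (0.053, 0.068 and 0.31), whereas that at 24 h held in each case. The 4 probes of the gene differed. Probe 1 changed by -1.65 at 0 h and -3.24 at 24 h, probe 3 by -0.83 and -2.04, and probe 4 by -0.93 and -2.06. Probe 2 was instead higher in FtsH3down, by 1.71 at 0 h (adjusted p = 2e-04) and 0.89 at 24 h (adjusted p = 0.0023). The antisense feature slr1604-as3 was not well above background on any of the 4 WT arrays and was well above it on the 4 FtsH3down arrays. It was at least 55.8-fold higher in FtsH3down at 0 h (adjusted p = 1.3e-06) and at least 59.7-fold higher at 24 h (adjusted p = 2.5e-07). Such bounds are given where a group was under the floor, that is, where no spot of the feature was well above background or the group's mean lay under the mean of its arrays' lowest signals well above background. They set the bright group's mean against the dim group's mean, in which each array counts as the higher of the feature's own signal and that lowest signal. No fold is given where both groups were under the floor. The 5'UTR of ftsH3 changed by -0.1 at 0 h (adjusted p = 0.63) and by -1.15 at 24 h (adjusted p = 4e-04). Of the 3 probes of slr1604-int1, probe 2 was higher in FtsH3down (0.89 at 0 h, adjusted p = 0.014, and 0.81 at 24 h, adjusted p = 0.017), and probes 1 (-0.75 and -1.05) and 3 (-0.9 and -1.74) were lower.

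**Figure D1:**
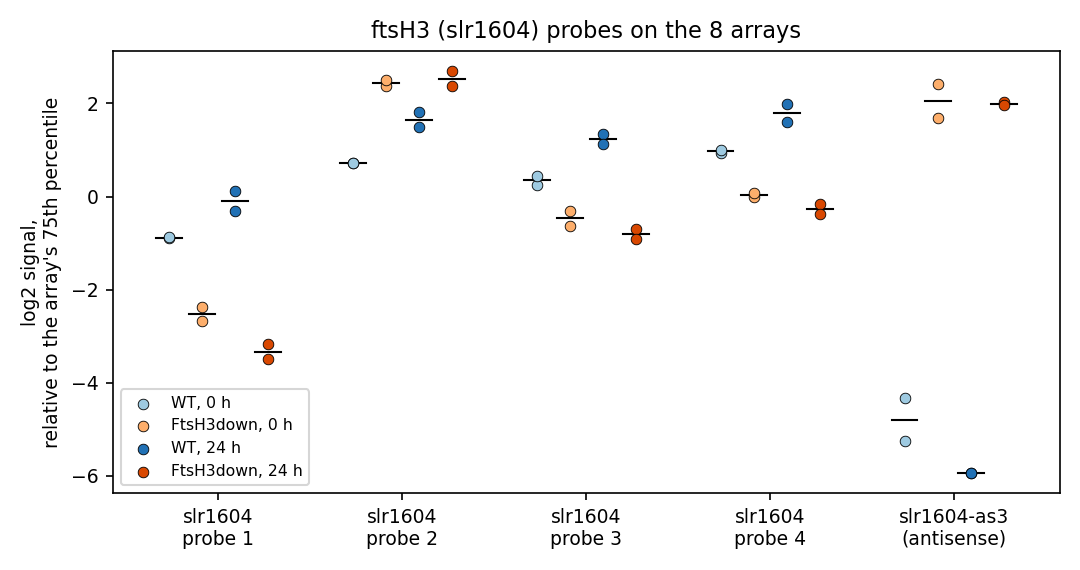
Log2 signal relative to the array's 75th percentile for the 4 probes of ftsH3 (slr1604) and the probe of slr1604-as3; points are arrays and short lines are means of the 2 arrays of a group. Probes 1, 3 and 4 were lower in FtsH3down than in WT at both times, while probe 2 (by 1.71 and 0.89) and slr1604-as3 were higher.

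The first comparison asked how the strains differed under standard conditions. Only these 2 strains were measured, with ammonium in every culture. Effects of the knockdown and of other differences between the strains can therefore not be told apart, here and in the comparisons below. Genes of phosphate acquisition were strongly reduced. The phosphate-binding protein gene pstS2 was at least 30.2-fold lower in FtsH3down (adjusted p = 5.3e-07), and the alkaline phosphatase gene phoA was at least 21.4-fold lower (adjusted p = 2.1e-07). All 12 genes of the phosphate stress list (Pho regulon) fell, with a median of -4.17. The transporter genes pstC1 (-4.45 ± 0.12), pstS1 (-4.32 ± 0.17), pstC2 (at least 13.7-fold lower) and pstA1 (-4.06 ± 0.13) were among them. The nuclease gene nucH was not well above background in FtsH3down and was at least 6.67-fold lower (adjusted p = 4.1e-06), and with the 4 genes under the floor at their bound the list's median was -3.68. The 5'UTRs of the pst genes sll0680 (-4.6 ± 0.12) and sll0681 (-4.28 ± 0.13) moved alike. Of the regulators listed with these responses, fur, which encodes the ferric uptake repressor, fell by 1.52 on the log2 scale (adjusted p = 8.2e-05), as did sphU (at least 1.05-fold lower), sphR (-0.86) and, picked out after its value was seen, sphS (-0.37), whereas pfsR was higher (0.63). All 4 genes of FtsH proteases fell, with ftsH2 at -1.61 ± 0.48, ftsH1 at -0.84 ± 0.12 and ftsH4 at -0.63 ± 0.12, but 2 of the 4 passed without WT replicate 1 or 2 or FtsH3down replicate 2 at 0 h.

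**Figure D2:**
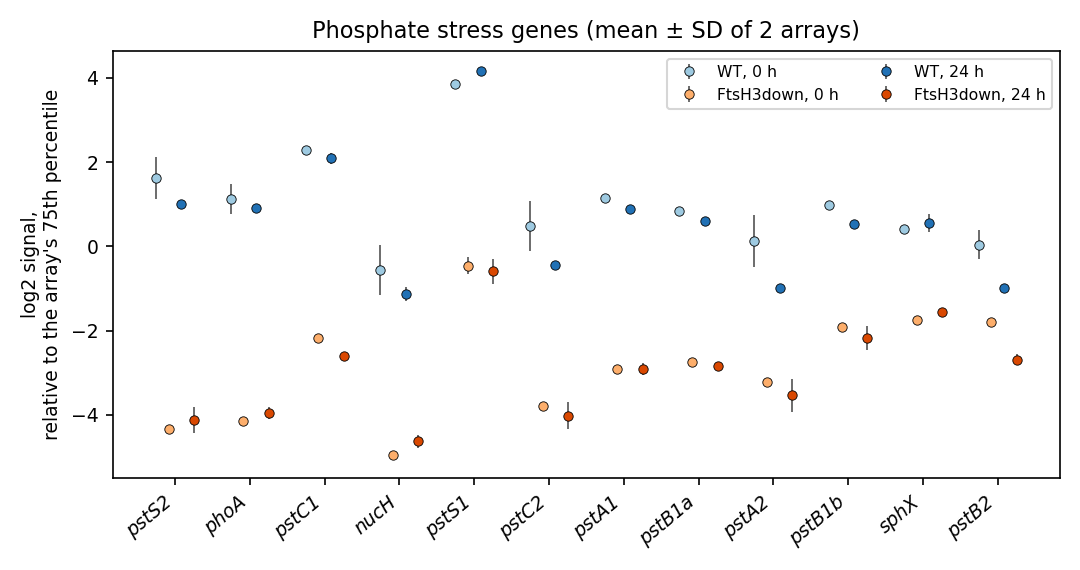
Log2 signal relative to the array's 75th percentile for the 12 genes of the phosphate stress list in the 4 groups. Means are shown with the SD of the 2 arrays of a group as bars. All 12 genes were lower in FtsH3down than in WT at both times. The medians of the fitted changes against WT were -4.17 at 0 h and -3.53 at 24 h. In FtsH3down, 4 genes at 0 h and 8 at 24 h were under the floor. With these at their bound the medians were -3.68 and -2.95.

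Genes of translation and photosynthesis were also reduced at 0 h, when 1565 of all 3299 protein-coding genes were lower and 651 higher. Of the lists in this paragraph, ribosomal proteins, phycobilisome, tetrapyrrole synthesis and the NDH-1 complex shifted against other protein-coding genes by camera at the preset correlation. The others did not (adjusted p from 0.0716 for ATP synthase to 0.301 for photosystem I). All 30 ribosomal protein genes fell, with a median of -2.15, and rpl12 (-3.17 ± 0.39) and rps12 (-2.73 ± 0.26) changed the most. All 13 phycobilisome genes, which encode the light-harvesting antenna, fell with a median of -1.52, and the linker gene cpcG2 (-3.88 ± 0.29) and cpcB (-2.19 ± 0.38) led them. Of 23 genes of tetrapyrrole and chlorophyll synthesis, 18 fell and 0 rose, with chlL (-2.4 ± 0.24) and por (-2.14 ± 0.3) the furthest. Of 16 genes of the NDH-1 complex, 14 fell and 0 rose, among them ndhA (-1.61 ± 0.19) and ndhD2 (at least 1.91-fold lower). All 9 ATP synthase genes (atpH, -2.32 ± 0.49) fell, as did 17 of 23 photosystem II genes (psbV, -2.05 ± 0.15), 8 of 12 photosystem I genes (psaF, -1.91 ± 0.24), 9 of 12 genes of cytochrome b6f and soluble carriers (petF, -3.03 ± 0.37) and 7 of 8 carboxysome and Rubisco genes (ccmK2, -1.9 ± 0.21). The members that rose against these falls were psbJ (0.48), psbK (0.54), psbM (1.39), psaE (0.63), petC3 (1) and rbcL (0.43), which were picked out after their values were seen. The genes with the largest increases were sll7067 (at least 26.6-fold, adjusted p = 1.2e-06) and sll1862 (4.55 ± 0.16, adjusted p = 2.5e-07). Among non-coding features, Spacer15-2-x was at least 469-fold higher and Spacer15-1-x at least 318-fold higher (both adjusted p = 2.9e-08), and neither was well above background in WT.

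Iron genes moved less at 0 h, and in both directions. Of 26 tested genes of iron acquisition and iron stress, 6 were higher and 8 lower, and the lower ones included the ferrous iron transport gene feoA (-1.18 ± 0.14), futA2 (-1.09 ± 0.13) and futB (-1.08 ± 0.14). The list's median was 0.3, or -0.19 without the 10 members under the floor in both strains and with 2 others at their bound. Its mean was -0.01, and it did not shift against other genes (camera adjusted p = 0.149). In iron storage, bfrA (-0.51) and bfrB (-0.43) fell and mrgA did not pass (-0.05). In iron-sulfur cluster assembly, sufR (1.02 ± 0.15) and sufA (0.8) rose while sufD (-0.58), sufC (-0.48) and sufE (-0.36, picked out after its value was seen) fell. That list's median was -0.22 against a mean of 0.01, and its median changed sign under 1 of 5 other scalings. Of 16 nitrogen control genes, glnB (1.4) rose and 7 fell, including glnA (-1.61) and icd (-1.56). Of 12 genes of inorganic carbon uptake, cmpA (0.68) and cupA (0.36) rose and ndhD3 (at least 1.27-fold) and sll1735 (-0.57) fell. Of 21 genes of chaperones and other proteases, hspA (1.46), clpB1 (0.82), dnaK3 (0.49) and htpG (0.44) rose, the last 3 picked out after their values were seen, and 10 fell, with htrA (at least 3.3-fold) first. Of 16 genes of high light and oxidative stress, perR (0.48, picked out after its value was seen) rose and 8 fell, with flv1 (-1.71) first. Of 9 sigma factor genes, sigD (0.81) and sigF (0.73) rose and sigG (-1.16), sigA (-0.85), sigI (at least 1.03-fold) and sigH (-0.68) fell, with sigF and sigH picked out after their values were seen. Of 18 genes of metal homeostasis other than iron, 6 rose, with the copper-resistance genes copM (at least 5.14-fold) and copR (1.78) first, and 6 fell (zur, -0.82). Of 10 hydrogenase and respiratory oxidase genes, 7 fell and 0 rose, with cydB (at least 3.46-fold) first. Leaving out 1 array of 0 h moved some of these counts by over 1.5 times. Without WT replicate 2 or FtsH3down replicate 2, the falls in iron storage and iron-sulfur assembly and all calls in inorganic carbon uptake were lost. The falls in iron-sulfur assembly were also lost without WT replicate 1. The 6 higher iron genes became 2 without WT replicate 2 and 3 without FtsH3down replicate 2, and the 10 lower chaperone and protease genes became 5 without either, while the 4 higher ones became 2 without WT replicate 1. The 6 higher genes of metal homeostasis became 3 without WT replicate 2, and the 7 lower hydrogenase and oxidase genes became 4 without WT replicate 1 or FtsH3down replicate 2.

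At 0 h, 5688 of 8228 features passed, 3088 higher and 2600 lower in FtsH3down, and 2777 of them changed by at least 1 on the log2 scale. A fit on only the 4 arrays of that slide gave 5869. The share of higher features was 54.3%, against 67.3% when arrays were scaled on protein-coding genes alone. By camera, 5 of 22 lists shifted, and all 5 shifted down: Pho regulon and ribosomal proteins (both adjusted p = 3.54e-06), tetrapyrrole synthesis (0.00361), phycobilisome (0.0122) and NDH-1 complex (0.0433). With an estimated correlation each of these lists had adjusted p = 0.657, and 0 lists passed by camera even at an unadjusted p of 0.05, while fry, which asks only whether a list's genes move one way, called 18. The other 17 lists had adjusted p between 0.0716 (ATP synthase) and 0.993 (chaperones and other proteases). Adjusted over the list alone, counts were equal except for iron acquisition (5 higher), iron-sulfur assembly (0 lower), inorganic carbon uptake (0 in either direction) and photosystem I (9 lower).

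The second comparison asked how the strains differed after 24 h of iron depletion. Genes that take up iron were now far lower in FtsH3down. Of 26 iron genes, 22 fell and 2 rose, with a median of -1.96, or -2.18 with members under the floor at their bound. The siderophore receptor gene fhuA (-4.47 ± 0.35, adjusted p = 9.6e-06), the transport-energising genes exbD1 (-3.8 ± 0.22) and exbB1 (-3.42 ± 0.18), and isiA (-3.45 ± 0.55, adjusted p = 0.00052), which encodes the iron-stress chlorophyll protein, led the falls. The members called higher, fhuA4 and fecB3, were picked out after their values were seen and have no fold, since FtsH3down was under the floor for both. The 12 Pho genes were again all lower, with a median of -3.53 (-2.95 with 8 genes at their bound), and pstS2 (at least 12.3-fold), phoA (at least 11.6-fold), pstS1 (-4.75 ± 0.17) and pstC1 (-4.69 ± 0.12) were among the most changed. Genes of other stress responses were low as well. Of 16 genes of high light and oxidative stress, 13 fell with a median of -2.58 (-2.51 at bounds), among them pgr5 (at least 10.2-fold lower, adjusted p = 2.5e-07), hliA (-4.2 ± 0.59) and hliC (-4.08 ± 0.39), whose FtsH3down arrays differed, and sll0218, picked out after its value was seen, was called higher though under the floor in both strains. Of 21 chaperone and protease genes, 15 fell with a median of -1.46, including htrA (at least 10.0-fold lower, adjusted p = 2.2e-07), the small heat-shock protein gene hspA (-3.48 ± 0.3) and clpR (-3.23 ± 0.21), while dnaK3 (0.38) and clpB2 (1.27) rose, both picked out after their values were seen. Without FtsH3down replicate 1 or 2 at 24 h the change was -5.22 or -3.19 for hliA, -4.72 or -3.44 for hliC and -3.87 or -5.08 for fhuA.

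Ribosomal protein genes remained low at 24 h, with all 30 lower and a median of -2.11 (rpl12, -3.95 ± 0.39), and all 30 of them had also been lower at 0 h. Of 16 NDH-1 genes 15 were lower, with a median of -1.13 (ndhD2, at least 5.88-fold), 13 of them at both times. Photosynthesis genes moved in both directions at 24 h. Of 9 ATP synthase genes 4 fell and 0 rose, but 7 fell without FtsH3down replicate 1 at 24 h, where atpG (-0.76 with all arrays) was -1.53 and atpD (-0.45) was -1.09, against 0.01 and 0.2 without replicate 2, where atpF rose. These 3 genes were picked out after their values were seen. Of 12 genes of cytochrome b6f and soluble carriers 9 fell, all 9 lower at 0 h too, and 3 rose. In the phycobilisome list 6 of 13 rose, led by the rod linker genes cpcC1 (2.71 ± 0.16) and cpcC2 (2.14 ± 0.17), and cpcG1 (-0.78), apcA (-0.98) and apcB (-1.02), picked out after their values were seen, fell. In photosystem I, psaI (2 ± 0.18) and psaE (1.84 ± 0.21) rose while psaF (-1.57 ± 0.24) fell, and in tetrapyrrole synthesis chlB (2.72 ± 0.13) rose while por (at least 2.09-fold) fell. In photosystem II, psbM (2.76 ± 0.23) rose and psbA3 (-1.89 ± 0.33) and psbA2 (-1.85 ± 0.34) fell. All 4 FtsH genes fell, with ftsH2 at -2.39 ± 0.48, ftsH1 at -2.37 ± 0.12 and ftsH4 at -1.07 ± 0.12. The regulator gene fur (-1.24 ± 0.16), sphR (-1.19) and sphS (-0.53) were lower, sphU was at least 1.55-fold lower, and pfsR, picked out after its value was seen, was called higher but has no fold, since FtsH3down was under the floor. Other falls included mrgA (-1.84), sufB (-2.37), glnA (at least 9.48-fold), petF (-2.94), sigH (-3.05) and cydB (at least 1.58-fold). Genes such as copM (2.5), copR (2.22), glnB (1.61) and rbcL (1.31) rose. Other genes among the most changed were slr1634 (8.15 ± 0.5) and ssl2384 (at least 25.8-fold), which were higher, and sll0330 (at least 73.7-fold) and sll1483 (-4.63 ± 0.29), which were lower. The non-coding features Spacer14-2-x and Spacer18-2-x were at least 2360-fold and at least 1770-fold higher. Without FtsH3down replicate 1 or 2 at 24 h the change was -3.3 or -1.49 for ftsH2, -4.65 or -3.24 for rpl12 and -3.65 or -2.24 for petF. Without WT replicate 1 or 2 at 24 h it was 9.02 or 7.27 for slr1634 and 3.26 or 1.74 for copM.

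At 24 h, 6298 features passed, 3782 higher and 2516 lower, and 3718 changed by at least 1 on the log2 scale. A fit on the 4 arrays of that slide gave 6002. The share of higher features was 60.1%, against 70.4% with scaling on protein-coding genes alone, and the FtsH3down arrays of this time had the fewest spots well above background. By camera 6 lists shifted, all down: ribosomal proteins (adjusted p = 8.6e-06), Pho regulon (2.16e-05), iron acquisition (7.91e-05), high light and oxidative stress (0.00357), NDH-1 complex (0.00504) and chaperones and other proteases (0.0105). Each had adjusted p = 0.529 with an estimated correlation, where 0 lists passed by camera even at an unadjusted p of 0.05, and fry called 16. The other 16 lists had adjusted p between 0.0673 (FtsH proteases) and 0.945. In nitrogen control, carboxysome and Rubisco, and tetrapyrrole synthesis, the median, mean and test differed in sign. The median changed sign under 3 of 5 other scalings for nitrogen control and phycobilisome, and under 1 for carboxysome and Rubisco, photosystem I and tetrapyrrole synthesis. Adjusted over the list alone, counts were equal except for nitrogen control (4 higher and 3 lower against 5 and 4, with 3 higher without WT replicate 2 or FtsH3down replicate 1 at 24 h), photosystem I (2 lower against 3) and the hydrogenase and oxidase list (9 lower against 8).

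The third comparison asked how WT responded to 24 h of iron depletion. Iron-stress genes rose by the largest amounts. The isiA transcript rose 773-fold (9.59 ± 0.55, adjusted p = 6.9e-06), but at least 1340-fold without WT replicate 1 at 0 h, where the other array was under its floor, and 396-fold without WT replicate 2 at 0 h, and the flavodoxin gene isiB rose at least 143-fold (adjusted p = 5.6e-07). The genes fhuA (at least 114-fold), exbB1 (at least 80.8-fold), isiC (at least 75.9-fold) and exbD1 (at least 44.1-fold) rose as well. Of 26 iron genes, 21 rose with a list median of 3.75 (3.68 with members under the floor at their bound), and fecB2 (-0.72) and fhuA4 (no fold, under the floor at both times), picked out after their values were seen, fell. IsrR-0-x, named for the antisense RNA of isiA, fell at least 339-fold (adjusted p = 5.5e-08). Of 10 genes of iron-sulfur cluster assembly, 9 rose with a median of 0.92, led by sufB (3.14 ± 0.14) and sufR (2.56 ± 0.15). In iron storage mrgA (1.94 ± 0.14) rose and bfrB (-0.54) fell. Of 21 chaperone and protease genes, 16 rose, with hspA (5.53 ± 0.3) and htpG (2.39 ± 0.12) first, and clpB2 (-1.43, picked out after its value was seen) fell. Of 16 genes of high light and oxidative stress, 12 rose and 0 fell, with pgr5 (at least 22.2-fold) and hliA (4.62 ± 0.59) first. Sigma factor genes sigB (2.15), sigH (2.11), sigC (1.31) and sigD (0.49) rose, and sigE (-0.83) and sigI (-0.49) fell, with sigD and sigI picked out after their values were seen. The FtsH genes ftsH1 (1.52 ± 0.12), ftsH3 (0.85 ± 0.14, adjusted p = 0.0014) and ftsH4 (0.63 ± 0.12) rose, ftsH2 did not pass (0.48 ± 0.48), and fur fell by 0.83 on the log2 scale (adjusted p = 0.0026).

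Light-harvesting genes fell in WT. All 12 photosystem I genes fell with a median of -1.81, including psaB (-2.19 ± 0.22) and psaC (-2.19 ± 0.21). Of 13 phycobilisome genes, 12 fell with a median of -2.49, led by cpcG2 (at least 46-fold), and apcD did not pass (-0.04). In tetrapyrrole synthesis 18 of 23 fell, with chlL (at least 28.4-fold), chlN (at least 14.9-fold) and chlB (-2.98 ± 0.13) first, and hemH (0.42, picked out after its value was seen) rose. All 8 carboxysome and Rubisco genes fell (ccmM, -1.4 ± 0.16), as did 15 of 23 photosystem II genes (psbO, -1.87 ± 0.21) and 8 of 9 ATP synthase genes (atpG, -1.65 ± 0.41), of which 3 fell without WT replicate 2 at 24 h and 5 without WT replicate 1 or 2 at 0 h. Of the 12 Pho genes 5 fell, with pstA2 (-1.12 ± 0.28), pstB2 (-1.03 ± 0.18), pstC2 (-0.93 ± 0.26) and pstS2 (-0.62 ± 0.23) first, then pstB1b (-0.46, picked out after its value was seen), and 7 did not pass. Of the Pho genes 3 fell without WT replicate 1 at 24 h and 1 without WT replicate 2 at 24 h or WT replicate 1 at 0 h. The genes slr1485 (at least 37.8-fold higher), sll1549 (at least 74.9-fold higher), ssl2384 (at least 22.1-fold lower) and slr1634 (-5.41 ± 0.5, and -6.28 or -4.53 without WT replicate 1 or 2 at 24 h) were among the most changed of any kind. In WT 4604 features passed, 1559 higher and 3045 lower, and 1944 changed by at least 1 on the log2 scale. The share of higher features, 33.9%, depended on the scaling and was 47.2% with normexp correction, 48.4% with quantile normalisation, 46% with median scaling and 46.8% with the deposited matrix.

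By camera, 12 lists shifted in WT. Those that shifted up were iron acquisition (adjusted p = 8.25e-18, and 0.175 with an estimated correlation), chaperones (1.35e-08, and 0.282), high light and oxidative stress (1.74e-07, and 0.277), iron-sulfur assembly (7.74e-06, and 0.16), FtsH proteases (0.00973, and 0.322), sigma factors (0.0308, and 0.361) and NDH-1 complex (0.0375, and 0.609). In the NDH-1 list ndhD2 (2.29 ± 0.37), ndhO (1.04), ndhJ (0.66) and ndhI (0.55, picked out after its value was seen) rose (2 genes without WT replicate 2 at 24 h), and ndhN (-0.57) fell, and this list's call, with a median of 0.12, was lost against all features (0.0542) and with fry (0.281). Those that shifted down were phycobilisome (0.000131, and 0.467), photosystem I (0.000995, and 0.462), tetrapyrrole synthesis (0.00301, and 0.282), photosystem II (0.0308, and 0.565) and carboxysome and Rubisco (0.0354, and 0.565). With an estimated correlation camera called 0 lists, 3 lists had an unadjusted p under 0.05, and fry called 18. The other 10 lists, Pho regulon among them (0.522), had adjusted p between 0.0983 and 0.907. For cytochrome b6f and soluble carriers the median (-0.27) and the test differed in sign, and the median of the metal homeostasis list changed sign under 3 of 5 other scalings. Adjusted over the list alone, counts were equal except for iron acquisition (22 higher), Pho regulon (3 lower), chaperones (17 higher), sigma factors (6 higher), ATP synthase (9 lower) and hydrogenase and oxidases (8 lower against 6, or 3 without WT replicate 1 at 0 h).

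The fourth comparison asked the same of FtsH3down, in which fewer features passed. The iron genes rose here too. The isiA transcript rose at least 72.4-fold (adjusted p = 0.00027), isiB at least 16.6-fold (adjusted p = 1.4e-05), exbB1 at least 5.5-fold, isiC at least 5.49-fold and exbD1 at least 2.31-fold, and feoA (3.99 ± 0.14) and futA2 (3.74 ± 0.13) rose. Of 26 iron genes, 19 rose with a median of 1.64 (1.57 at bounds), and fecB2 (at least 1.35-fold, picked out after its value was seen) fell. In iron-sulfur assembly sufB (1.07 ± 0.14), sufC (0.89) and sufR (0.65) rose. Photosystem I genes fell in 8 of 12 cases with a median of -0.76 (psaF, -1.26 ± 0.24), phycobilisome genes in 10 of 13 with a median of -0.9 (cpcG2, at least 1.29-fold), and hydrogenase and oxidase genes in 8 of 10 with a median of -0.87, or -0.47 at bounds (ctaD1, -1.03 ± 0.22). Ribosomal protein genes fell in 6 of 30 cases (rpl18, -1.17 ± 0.32), with a median of -0.63. In WT 15 of the 30 had fallen with a median of -0.84, and the median difference between the responses was 0.04. The counts in FtsH3down depended on single arrays. Without WT replicate 1 or 2 at 24 h, 5 photosystem I genes, 3 ribosomal protein genes and 5 hydrogenase and oxidase genes fell, and without WT replicate 1 or 2 at 0 h, 5 phycobilisome genes and 5 hydrogenase and oxidase genes did. Ribosomal protein genes that fell numbered 27 or 1 without FtsH3down replicate 1 or 2 at 24 h and 0 without either at 0 h. Without FtsH3down replicate 2 at 24 h 3 photosystem I and 5 phycobilisome genes fell, without FtsH3down replicate 1 at 0 h 2 photosystem I, 1 phycobilisome and 4 hydrogenase and oxidase genes, and without FtsH3down replicate 2 at 0 h 5 of the last. The chlorophyll gene chlL fell at least 2.21-fold and chlN at least 1.57-fold. Of the Pho genes pstB2 (at least 1.72-fold) and pstC1 (-0.44 ± 0.12) fell and 10 did not pass, and the list's median of -0.12 changed sign under 2 of 5 other scalings. By limma 0 of the 4 FtsH genes passed (1 at an unadjusted p of 0.05), with ftsH3 at -0.34 ± 0.14 (adjusted p = 0.14) and ftsH1 at -0.01 ± 0.12 (adjusted p = 0.96), and fur fell by 0.55 on the log2 scale (adjusted p = 0.046). The genes slr1485 (at least 8.73-fold) and sll1549 (at least 17.8-fold) were again among the most raised.

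In FtsH3down 1615 features passed between the times, 598 higher and 1017 lower, and 452 changed by at least 1 on the log2 scale. Without FtsH3down replicate 1 or 2 at 0 h the count was 1072 or 922. The share of higher features was 37%, against 61.5% with median scaling and 47.1% with scaling on protein-coding genes. By camera 7 lists shifted. Iron acquisition (adjusted p = 3.05e-22, and 0.209 with an estimated correlation), iron-sulfur assembly (0.00118, and 0.209) and chaperones (0.00269, and 0.852) shifted up. Photosystem I (0.000511, and 0.758), phycobilisome (0.000511, and 0.852), hydrogenase and oxidases (0.000511, and 0.309) and ribosomal proteins (0.00194, and 0.965) shifted down. In the chaperone list htpG (0.47) and clpX (0.41) rose, and the median was 0.17, but the call was lost against all features (0.0608) and with fry (0.277). Those of phycobilisome (0.0507) and ribosomal proteins (0.299) were lost with fry. With an estimated correlation camera called 0 lists, 3 had an unadjusted p under 0.05, and fry called 5. The other 15 lists had adjusted p between 0.231 and 0.925. The median, mean and test differed in sign for FtsH proteases, high light and oxidative stress, sigma factors and metal homeostasis. The median changed sign under 5 of 5 other scalings for high light and oxidative stress, under 3 for tetrapyrrole synthesis and metal homeostasis, under 2 for FtsH proteases and under 1 for NDH-1 complex. Adjusted over the list alone, counts were equal except for ribosomal proteins (11 lower), phycobilisome (12), photosystem I (10), chaperones (0 higher), nitrogen control (1 higher and 6 lower against 0 and 5, with 3 lower without WT replicate 1 or 2 at 24 h, and 2 or 1 without FtsH3down replicate 1 or 2 at 0 h), inorganic carbon uptake (1 higher against 0), and carboxysome, photosystem II and NDH-1 (0 lower against 1 each).

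The fifth comparison tested whether the response to iron depletion differed between the strains. The fitted rise of iron genes was smaller in FtsH3down. The difference in response was -4.46 ± 0.5 for fhuA (adjusted p = 0.00059), -4.16 ± 0.31 for exbD1, -3.9 ± 0.32 for isiC, -3.86 ± 0.25 for exbB1 (adjusted p = 0.00012) and -3.25 for isiA (adjusted p = 0.0137, picked out after its value was seen). Both strains were under the floor at 0 h for fhuA, exbD1, isiC and exbB1, and FtsH3down was for isiA, so that these differences are neither exact sizes nor bounds. That of isiA was -4.21 without WT replicate 1 at 0 h and -2.28 without WT replicate 2 at 0 h, and that of fhuA was -3.85 or -5.07 without FtsH3down replicate 1 or 2 at 24 h. All 21 iron genes that rose in WT changed less in FtsH3down, 19 of them past the threshold for the difference, and 19 of them still rose there. Their median ratio of log2 changes, FtsH3down to WT, was 0.47 (range -0.13 to 0.92), and 0.47 also over the 10 of them not under the floor in any group. The list's median difference was -1.78, or -1.46 over its members not under the floor in any group. The exceptions, feoA (-0.37, adjusted p = 0.177) and sll1408 (-0.34, adjusted p = 0.353, under the floor in both strains at 0 h), were also picked out after their values were seen, as were exbD2 and fhuA2, which did not rise in FtsH3down, where fhuA2 was under the floor at both times. IsrR-0-x was 4.5 ± 0.11 in WT and 5.87 ± 0.25 in FtsH3down at 0 h, and -4.23 ± 0.17 and 5.48 ± 0.02 at 24 h (SD, n = 2 arrays), a difference in response of 8.34 ± 0.22 (adjusted p = 1.7e-06) whose size is inexact, since WT was under the floor (-3.9) at 24 h.

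**Figure D3:**
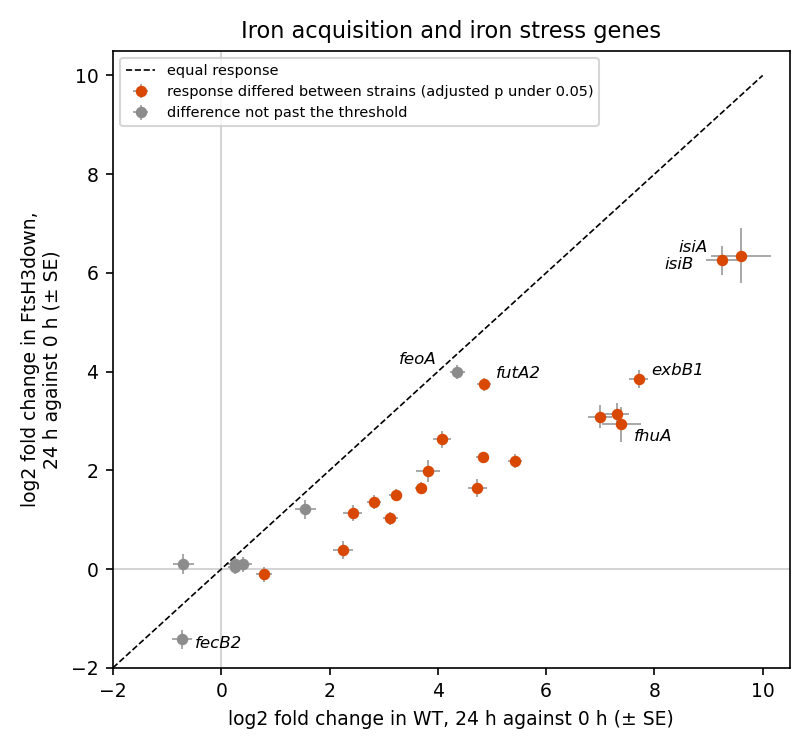
Log2 change from 0 h to 24 h of iron depletion in WT (x axis) and in FtsH3down (y axis) for the 26 tested genes of iron acquisition and iron stress; each point is a gene and bars are the SE of the fit. All 21 genes that rose in WT lie below the line of equal change, with the fitted change of isiA at 9.59 in WT and 6.35 in FtsH3down, where its 0 h group was under the floor.

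In other lists of stress genes part of the members had negative differences. They passed for 12 of 16 genes of high light and oxidative stress (pgr5, -4.76 ± 0.27, and hliA, -3.64 ± 0.84), for 10 of 21 chaperone and protease genes (hspA, -4.93 ± 0.42, and htrA, -2.55 ± 0.23), for 4 of 9 sigma factor genes (sigH, -2.37 ± 0.2, sigB, -1.74, sigA, -1.5, and sigC, -0.89) and for 5 of 10 genes of iron-sulfur assembly (sufB, -2.07 ± 0.2, sufR, -1.91, sufE, -0.93, sufA, -0.87, and sufS, -0.68, the last picked out after its value was seen). In the same lists clpB2 (1.52), sigE (0.75) and sigI (0.57), picked out after their values were seen, passed in the other direction. Without FtsH3down replicate 1 or 2 at 24 h the difference was -4.65 or -2.63 for hliA, and it was -1.69 (adjusted p = 0.0045) or 0.12 for ftsH2. The genes ftsH1 (-1.53 ± 0.17) and ftsH3 (-1.19 ± 0.2, adjusted p = 0.0035) also passed, whereas ftsH2 (-0.79 ± 0.68), ftsH4 (-0.44 ± 0.17) and fur (0.28 ± 0.23) did not pass. Positive differences passed for 10 of 13 phycobilisome genes (cpcG2, 5.08 ± 0.42, and cpcC1, 3.22 ± 0.23), 15 of 23 genes of tetrapyrrole synthesis (chlN, 3.19 ± 0.29, chlL, 2.93 ± 0.34, and chlB, 2.58 ± 0.19), 7 of 12 photosystem I genes (psaI, 1.62 ± 0.26), 11 of 23 photosystem II genes, 6 of 8 carboxysome and Rubisco genes (ccmM, 1.47 ± 0.22) and 2 of 9 ATP synthase genes (atpF, 1.48, and atpE, 0.81). In these lists hemH (-0.61, picked out after its value was seen) alone passed as negative. Leaving out 1 array lowered the count for carboxysome and Rubisco (without WT replicate 1 at 24 h or WT replicate 1 or 2 at 0 h). It lowered those for photosystem I and photosystem II (without WT replicate 2 at 24 h or WT replicate 1 at 0 h), and for photosystem II also without WT replicate 2 at 0 h. With all arrays the differences of the 9 ATP synthase genes were all positive (0.39 to 1.48), but their values moved up or down with the array left out. The differences of atpI, atpG, atpD and atpC, picked out after their values were seen, were 0.97, 1.11, 1.12 and 0.78. Without FtsH3down replicate 1 at 24 h they were 0.22, 0.34, 0.47 and 0.12, and without replicate 2 they were 1.72, 1.88, 1.77 and 1.44. Fewer sigma factor genes passed as negative when any single WT array or FtsH3down replicate 1 at 0 h was left out. By limma 0 of the 12 Pho genes passed (2 at an unadjusted p of 0.05), and nucH (0.9 ± 0.35, adjusted p = 0.077) came nearest. Outside the lists, ssl2384 (5.51 ± 0.24) and slr1634 (5.35 ± 0.71, and 6.23 or 4.48 without WT replicate 1 or 2 at 24 h) differed in one direction and sll0330 (-7.02 ± 0.36) and ssl0452 (-3.92 ± 0.24) in the other. Of these genes pgr5, htrA, sigI, cpcG2, chlN, chlL, nucH, ssl2384 and sll0330 had at least 1 group under the floor, so that their differences are neither exact sizes nor bounds.

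**Figure D4:**
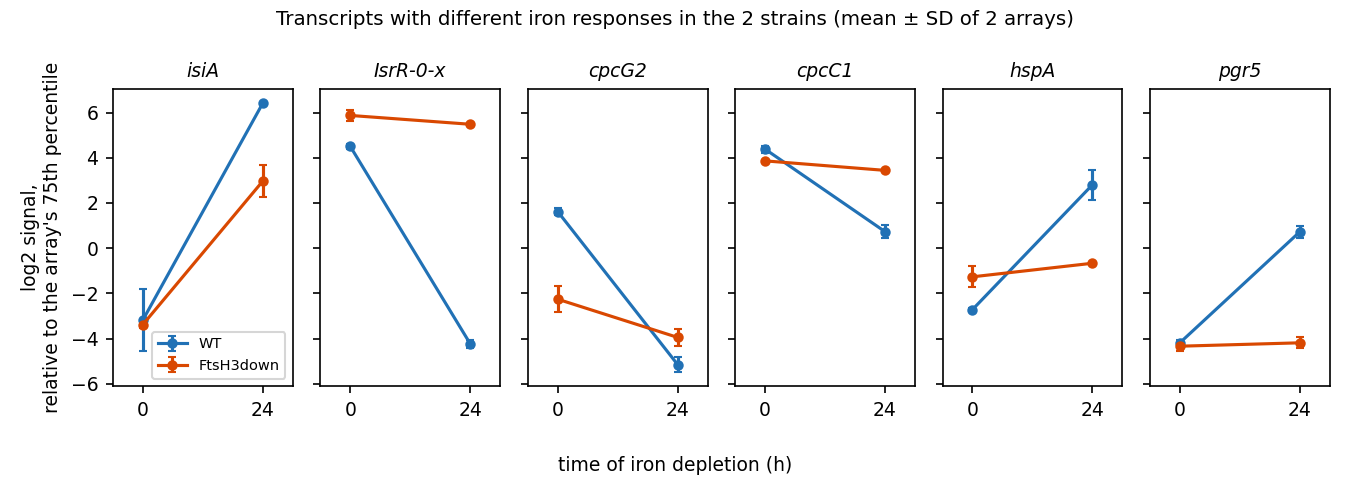
Log2 signal relative to the array's 75th percentile for isiA, IsrR-0-x, cpcG2 and other named features in the 4 groups. Points are means and bars are the SD of 2 arrays, and lines join 0 h and 24 h in each strain. IsrR-0-x fell at least 339-fold in WT and stayed near its starting level in FtsH3down, at 5.87 and 5.48.

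A difference in response passed for 3055 features, 1968 with a positive and 1087 with a negative difference, and 1690 differed by at least 1 on the log2 scale. Without WT replicate 2 at 24 h or WT replicate 1 at 0 h the count was 1797 or 1892. The positive share was 64.4%, against 54% with normexp correction, 51.7% with quantile normalisation and 51.8% with the deposited matrix. By camera 11 lists shifted. The differences were negative for iron acquisition (adjusted p = 4.6e-12, and 0.253 with an estimated correlation), high light and oxidative stress (1.97e-06, and 0.253; median -1.46), chaperones (1.24e-05, and 0.416; median -0.7), iron-sulfur assembly (0.00076, and 0.253; median -0.68), FtsH proteases (0.0174, and 0.416; median -0.99) and NDH-1 complex (0.0326, and 0.716; median -0.45). The NDH-1 call was lost with fry (0.281). The differences were positive for phycobilisome (0.000153, and 0.522; median 1.76), tetrapyrrole synthesis (0.000396, and 0.253; median 0.7), photosystem I (0.0168, and 0.589; median 1.11), carboxysome and Rubisco (0.0311, and 0.599; median 0.84) and photosystem II (0.0319, and 0.634; median 0.72). With an estimated correlation camera called 0 lists, 4 had an unadjusted p under 0.05, and fry called 15. The other 11 lists, Pho regulon among them (0.63), had adjusted p between 0.0581 and 0.685.

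Among the lists without a shift in response, the median and the test differed in sign for cytochrome b6f and for ribosomal proteins. The median changed sign under 3 of 5 other scalings for inorganic carbon uptake and metal homeostasis, under 2 for cytochrome b6f and hydrogenase and oxidases, and under 1 for ribosomal proteins. In those lists nrsD (1.7 ± 0.21), sbtB (1.28 ± 0.22), sbtA (1.21 ± 0.18) and rpl3 (1.02 ± 0.34) had positive and pacS (-1.34 ± 0.17) and petE (-0.97 ± 0.29) negative differences, and glnA (-1.96 ± 0.35) of nitrogen control was also negative, with FtsH3down at 24 h under the floor for nrsD and glnA. Adjusted over the list alone, counts were equal except for iron acquisition (1 positive and 20 negative against 0 and 19), FtsH proteases (3 negative), iron-sulfur assembly (6), chaperones (12), phycobilisome (12 positive), tetrapyrrole synthesis (17), photosystem I (8), inorganic carbon uptake (5 positive and 1 negative against 4 and 0, with 2 positive without WT replicate 1 or 2 or FtsH3down replicate 2 at 24 h or replicate 1 of either strain at 0 h), cytochrome b6f (3 positive against 2) and ribosomal proteins (0 against 1).

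The strain differences at the 2 times correlated more closely than the iron responses of the 2 strains. Of features higher in FtsH3down, 2619 were higher at both times, against 1419 expected if independent, and of features lower 1802 were lower at both times, against 795 expected. Opposite calls numbered 91 of those higher and 250 of those lower at 0 h. Between the iron responses of WT and FtsH3down, 282 features rose in both strains (113 expected) and 663 fell in both (376 expected), with 61 and 88 opposite calls. Both iron responses compare the same 2 slides, so a slide effect would also raise the shared counts above those expected. These 2 counts depended on the choices. Features that rose in both numbered 545 with median scaling and 138 with the 4 arrays of each comparison alone. They numbered 180 and 172 without WT replicate 1 or 2 at 24 h, 475 and 184 without FtsH3down replicate 1 or 2 at 24 h, 172 and 164 without WT replicate 1 or 2 at 0 h, and 146 without FtsH3down replicate 2 at 0 h. Features that fell in both numbered 440 with quantile normalisation, 430 with median scaling, 429 with the 4 arrays alone, 428 and 436 without WT replicate 1 or 2 at 0 h, and 432 without FtsH3down replicate 2 at 0 h. Across features, log2 changes correlated with r = 0.82 between the strain differences at 0 h and 24 h and with r = 0.47 between the iron responses. By kind of feature, antisense RNAs were mostly higher in FtsH3down at 0 h (948 higher and 163 lower of 1599, median 0.58), whereas more protein-coding genes were lower than higher (651 higher and 1565 lower of 3299, median -0.34, or -0.09 with scaling on protein-coding genes). At 24 h the antisense median was 0.67 and the protein-coding median -0.15, which became 0.15 with scaling on protein-coding genes.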

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

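No test in this part was chosen after the result was seen, but the second part of the rule for the floor was added after the data were seen.

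Part of the genes of iron stress, other stress responses and light harvesting answered iron depletion differently in the strains, and a test of the difference between the responses drew attention to each result here. In all, 3055 features had a different response. The median difference in log2 response, FtsH3down minus WT, was -1.78 for iron acquisition and iron stress, -1.46 for high light and oxidative stress, -0.99 for FtsH proteases, -0.7 for chaperones and other proteases, -0.68 for iron-sulfur cluster assembly and -0.45 for the NDH-1 complex. It was 1.76 for the phycobilisome, 1.11 for photosystem I, 0.84 for carboxysome and Rubisco, 0.72 for photosystem II and 0.7 for tetrapyrrole and chlorophyll synthesis. Over members not under the floor in any group the median was -1.46 for iron acquisition and iron stress and -1.72 for high light and oxidative stress. With an estimated correlation, camera called 0 of these lists, and 4 of the 22 lists had an unadjusted p under 0.05.

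Among single genes the difference was negative for sll0330 (-7.02), hspA (sll1514, -4.93), pgr5 (ssr2016, -4.76), fhuA (sll1206, -4.46), exbD1 (sll1405, -4.16), ssl0452 (-3.92), isiC (sll0249, -3.9), exbB1 (sll1404, -3.86), sll0846 (-3.85) and hliA (ssl2542, -3.64). It was also negative for ftsH1 (slr1390, -1.53) and for the targeted gene ftsH3 (slr1604, -1.19). It was positive for ssl2384 (5.51), slr1634 (5.35), cpcG2 (sll1471, 5.08), slr1071 (3.77), slr1065 (3.55), slr1067 (3.4), slr1073 (3.3), sll0710 (3.3), cpcC1 (sll1580, 3.22) and slr1396 (3.22). Of the non-coding features it was positive for IsrR-0-x (8.34), sll0247-as2 (7.05), NC-1248 (5.3), slr1396-5'UTR (5.06) and sll1471-5'UTR (4.61). It was negative for ssl0452-5'UTR (-7.2), slr1489-5'UTR (-4.71), sll0249-int1 (-4.02), sll1406-int1 (-3.98) and sll0330-int1 (-3.76). Many of these had a group under the floor, so that their fitted difference is neither an exact size nor a bound. These were sll0330, pgr5, fhuA, exbD1, isiC, exbB1, ssl2384, cpcG2, slr1071, slr1065, slr1067, slr1073, sll0710, slr1396, IsrR-0-x, NC-1248, slr1396-5'UTR, sll1471-5'UTR, ssl0452-5'UTR, slr1489-5'UTR, sll0249-int1 and sll1406-int1.

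Leaving out 1 array moved the difference by over 1.5-fold for some, to -4.65 or -2.63 for hliA, -3.85 or -5.07 for fhuA (without FtsH3down replicate 1 or 2 at 24 h), 6.23 or 4.48 for slr1634 and 5.91 or 4.68 for NC-1248 (without WT replicate 1 or 2 at 24 h). For ssl0452-5'UTR it gave -8.03 or -6.38 without WT replicate 1 or 2 and -6 or -8.41 without FtsH3down replicate 1 or 2 at 0 h.

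An additive effect of the slide cancels in these differences, but an effect of the slide that differed between strains would not, and each time lay on a single slide. The FtsH3down arrays at 24 h had the fewest spots well above background (69.3% and 60.7%). Among features above background on all 8 arrays 2569 passed, and with quantile normalisation 2889 of all features tested did. No biological explanation was tested for these differences.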

How the results depend on the processing

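Scaling on protein-coding features, camera against all features, a filter on the compared groups and leaving out features near saturation were chosen only after the data were seen.

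The targeted transcript ftsH3 stayed lower in FtsH3down at 24 h in every setting but probe 2 on its own (0.89), with values from -1.78 to -1.45 when an array was left out. At 0 h its call was lost with median scaling (-0.33, adjusted p = 0.068), the deposited matrix (-0.25, 0.053) and scaling on protein-coding features (-0.18, 0.31), and probe 2 on its own was reversed (1.71). It ranged from -0.48 to -0.37 with arrays left out and missed the threshold without WT replicate 1 (0.084) or 2 (0.14) or FtsH3down replicate 1 (0.05) or 2 (0.11) at 0 h, where the lone array is assumed to vary like the other groups. Apart from these fewer arrays, the cause was not tested.

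The counts for FtsH3down against WT at 0 h and 24 h and for the iron response of WT stayed within 1.5 times in every setting but the stricter one of an absolute log2 change of at least 1, which gave 2777, 3718 and 1944. That threshold gave 452 for the iron response of FtsH3down and 1690 for the difference between responses, and adjusted p 0.01 gave 618 and 1575. For FtsH3down, the 4 arrays on their own gave 762, and a call of any probe gave 3020. The fit on 4 arrays had fewer degrees of freedom and used only the spread of FtsH3down, whose replicate arrays differed more than those of WT. Which of these lowered the count was not tested. Leaving out an array gave 922 to 2415 in FtsH3down (1072 and 922 without FtsH3down replicate 1 or 2 at 0 h) and 1797 to 3424 for the difference (1797 without WT replicate 2 at 24 h, 1892 without WT replicate 1 at 0 h). The replicate block gave 5592, 6268, 4552, 1523 and 2939. A slide term leaves the strain comparisons as they are and could not be fitted for the iron comparisons.

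Lists depended most on the set test. With an estimated correlation camera called 0 lists in each comparison. The adjusted p was then 0.66 for Pho at 0 h, 0.53 for iron and for Pho at 24 h, and for iron 0.17 in WT, 0.21 in FtsH3down and 0.25 for the difference. These are the highest of those lists' values over all settings, and the lowest were 1.9e-16, 2.8e-10, 3.3e-14, 6e-42, 1.1e-29 and 1.7e-24, each from single probes. At 0 h 11 lists passed with normexp, 11 with quantile normalisation, 12 with the matrix, 15 with single probes, 18 with fry and 11 against all features, and at 24 h 15, 16 and 10 with the last 3. The iron list at 0 h passed with the matrix (0.028) and single probes (0.026), and its values ran from 0.026 to 0.81. The Pho list in WT passed with fry (0.045; range 0.045 to 0.82), which asks a different question. The cause was not tested for the scalings.

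Overlaps at an absolute log2 change of at least 1 were 1295 and 807 for the strain differences and 72 and 158 for the iron responses. Features that rose in both strains numbered 545 with median scaling and 138 with the 4 arrays of each comparison alone. Leaving out an array gave 146 to 475, with 180 and 172 without WT replicate 1 or 2 at 24 h, 475 and 184 without FtsH3down replicate 1 or 2 at 24 h, 172 and 164 without WT replicate 1 or 2 at 0 h, and 146 without FtsH3down replicate 2 at 0 h. Features that fell in both numbered 440 with quantile normalisation, 430 with median scaling, 429 with the 4 arrays alone and 428 to 895 with an array left out (428 and 436 without WT replicate 1 or 2 at 0 h, 432 without FtsH3down replicate 2 at 0 h). The cause was not tested for the scalings.

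Of 477 calls of genes that the rule named, 396 kept direction and call in every setting that used all arrays, and 394 when any array was left out. Reversals, whose cause was not tested, were sll0030 in WT (0.02 with normexp, 0.01 with quantile normalisation), slr0395 (0.15, middle probe) and slr2043 (0.23 with the median of probes, 0.71 with the middle probe) in FtsH3down, and slr0044 in the difference (-0.16 with normexp, -0.13 with the matrix). Signal over background limits FtsH3down at 24 h most, where 69.3% and 60.7% of spots were well above it.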

Other observations

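The tests on Spacer features, on probe 2 of ftsH3 and on slr1604-as3 were chosen only after the result was seen, as were the families themselves.

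Features named Spacer were higher in FtsH3down almost throughout. Of 121 tested, 120 were higher at 0 h and 120 at 24 h, with medians of 4.02 and 4.7, or 3.84 and 4.46 with features below background at their bound. Under each of 6 scalings, 120 were higher at 0 h and 119 at 24 h. Scaling of the arrays moves features of like signal alike, yet the median Spacer change at 0 h exceeded that of other features by 5.43 when averaged over 10 bins (5.14 to 5.67 over the 4 pairs of arrays). The bins held features of like mean signal over all arrays of both strains, which need not be alike on each array. Each bin counted equally however few Spacer features it held, so that 5.43 is not the size of the excess. A floor of dim arrays is argued against as well, since 120 of 121 were higher by at least 1 on the log2 scale at 0 h with WT set to its floor where it was under it, and the 75 under the floor in neither strain were all higher. A sequence missing from the WT strain would leave no signal of its own there, yet 43 of 47 features with suffix 0 lay above background on all 4 WT arrays. For this, 1 spot well above background per array was enough. The count argues against a missing sequence only if no other RNA binds these probes, which was not examined. For suffixes 1 and 2, 27 of 74 lay above background on all 4 WT arrays and 35 below it on all 4. For these, a sequence missing from WT and a lower level in WT cannot be told apart. No biological explanation was tested.

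Non-coding features were higher in FtsH3down relative to protein-coding genes, and the difference of their median log2 changes at 0 h was 0.74. This differed by kind of non-coding feature. At 0 h the median change was 0.58 for antisense RNAs, 0.83 for features named NC and 0.16 for parts of genes. It was -0.16 for 5'UTRs, of which 209 were higher and 274 lower. For 276 features of other names, the Spacer features among them, it was 1.88. Of 3299 protein-coding genes 1565 were lower and 651 higher at 0 h, and of 4929 non-coding features 1035 were lower and 2437 higher. The direction of protein-coding genes by themselves is not fixed, since their median was -0.34 at 0 h and -0.15 at 24 h, but -0.09 and 0.15 with scaling on protein-coding genes. Among the brightest features (2065 non-coding and 678 protein-coding) it was 1.12 (0.98 to 1.27 over the 4 pairs of arrays), so that a floor or compression of dim signals is an unlikely source. Averaged over 10 bins of features of like mean signal the difference at 0 h was 0.8 (0.75 to 0.85). Genomic DNA in the FtsH3down RNA would lift equally dim features of either kind alike, and so would not make this gap by itself. Falls of protein-coding genes widen the gap with or without such DNA. The value can therefore not exclude that DNA added to the signals. A change in the RNA pool of the strain stays open and was not tested.

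At ftsH3 itself, probe 2 and slr1604-as3 were higher in FtsH3down while the other 3 probes were lower. Of slr1604-int1, probe 2 was higher too (0.89 at 0 h and 0.81 at 24 h) and probes 1 and 3 were lower. Probe 2 changed in WT by 0.92 from 0 h to 24 h, near the 0.79 to 0.89 of the other probes, which argues against a probe that does not report the gene in WT. In FtsH3down it changed by 0.1, against -0.8, -0.33 and -0.31 for probes 1, 3 and 4. The WT values can therefore not decide what probe 2 reports in FtsH3down. A transcript made by the construct of the FtsH3down strain, alike at both times, is a candidate explanation for slr1604-as3, which differed by -0.06 between the times in FtsH3down. As the construct is present in a single strain, this and an antisense RNA of the native gene cannot be told apart.

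Genes whose locus tag begins with the digit 7 were also mostly higher in FtsH3down, 71 of 93 at 0 h (median 0.92) and 78 of 93 at 24 h (median 1.33). Many of them were dim. Without the 21 genes at 0 h and 44 at 24 h that were under the floor in both strains, and with others at their bound, the medians were 1.01 and 1.54. The 6 genes from sll7062 to sll7067 were all higher, with medians of 3.16 and 3.7, or 3.12 and 3.02 at their bound. No explanation was tested for this family.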
